A study of Bos taurus with 18 samples.

How the data were processed

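RNA from milk somatic cells of 18 cows (6 healthy, 6 with mastitis, 6 with endometritis) was measured on Affymetrix bovine genome arrays, with 1 array per cow. Per the labels' protocols, animals came from farms and clinics, cells were collected from milk, and RNA was extracted with TRI reagent and treated with DNase. RNA with an integrity number above 6 was used. From 100 ng of total RNA, labelled RNA was made with the 3′ IVT Express kit, which primes at the poly-A tail, and 10 µg were hybridised. The submitters' processing notes name RMA, GCRMA and limma, with no version, role or order given. Which of RMA and GCRMA made the values, and the base of their logarithm, are not given in the sources used here. The deposited values run from 2.43 to 14.2 with a median of 2.55, a range and a pile-up at the floor that GCRMA gives on a log2 scale, and they were used as log2 values of normalised intensity as the authors deposited them. A fold change printed here rests on that reading. Raw intensity files were not used here.

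The table held 24128 probe sets, of which 112 are controls and 24016 were tested, and 0 columns belonged to no sample. Groups were taken from the labels. The platform annotation gave 1 gene symbol for 13292 probe sets, several for 86 and none for 10638, and no name was taken from a probe set with several. Symbols were checked through Entrez identifiers against a reference gene table of assembly ARS-UCD2.0, which was used only for names: 0 symbols were updated and 29 identifiers were absent from it. No coordinates are given, because no genome build is named for the probe sets. The named probe sets covered 9155 genes, 2913 of them with more than 1 probe set. A gene was represented by its probe set with the highest mean over all 18 arrays, chosen without regard to group.

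Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). A single model with a term for each of the 3 groups was fitted to all 18 arrays, so that the groups shared an estimate of the spread (15 residual degrees of freedom, prior degrees of freedom 0.561). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets within each comparison, and a probe set was called at an adjusted p under 0.05. No filter on dim probe sets was applied. A gene whose 6 arrays in a group were all at or under the median of 2.55 was taken as at background there, and its fold change was computed against that median and given as a lower bound.

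The 28 gene lists cover cell types (neutrophil, macrophage, T cell, NK and cytotoxic, B and plasma cell, mammary secretory, epithelial structure, erythroid), inflammation (cytokines and chemokines, anti-inflammatory mediators, Toll-like receptor and NF-kappaB pathway, antimicrobial and acute phase proteins, interferon response, MHC class I and class II presentation, complement, eicosanoid synthesis, phagocyte oxidase and oxidative defence, leukocyte adhesion and migration, matrix metalloproteinases and remodelling) and cell state (glycolysis and hypoxia, oxidative phosphorylation, milk fat and cholesterol synthesis, cell cycle, apoptosis and survival, ribosomal proteins, glucocorticoid response, immediate early and heat shock genes). The tests, the lists, the rule for named genes and all but 4 of the alternatives were fixed before the data were examined. Lists were tested with camera in limma at a preset correlation of 0.01 and with an estimated correlation beside it, adjusted over the 28 lists within each comparison. The fry test in limma was run as well, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. List scores per array, the mean of the members' centred log2 values, were compared with exact permutation tests over all 924 arrangements of 6 against 6, two-sided, for which the smallest possible p is 0.00216.

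Named genes are, per comparison, the 15 with the largest rise and the 10 with the largest fall among called genes with all 6 arrays of the first group on 1 side of the mean of the second. Where fewer than 5 genes were called, they are the 5 of each direction with the smallest p, given as values that did not pass. Up to 4 members of each list with the smallest p were added, and so were CXCL8, IL1B, TNF, IL6, TLR2, TLR4, CD14, SAA3, HP, LTF, LCN2, S100A8, S100A9, CXCR2, CSN2, CSN3 and LALBA. LCN2 and CXCR2 were not measured under those names. Any gene named outside this rule is marked in the text as chosen after its value was seen.

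The procedure was tested on data simulated for each comparison, with its group sizes and a spread taken from the arrays. In each, 50 of 24016 probe sets were moved by each size, all drawn from those with a mean above the median of 2.55. Of those moved by 0.5, 1, 2 and 3 log2 units, limma recovered 18%, 40%, 80% and 98% for mastitis against healthy, 22%, 42%, 86% and 100% for endometritis against healthy, and 8%, 56%, 88% and 96% for mastitis against endometritis. It called 5, 8 and 7 unchanged probe sets. No dim probe set, with a mean at or under 2.55, was moved, so recovery of dim probe sets was not measured and can be lower. The correlation between the disease differences was compared with simulations of unchanged groups that share their controls, and with 20 assignments that give each disease its own 3 controls. To test scaling by the authors, each list member was set beside the 50 genes outside the list nearest in mean level over the 12 arrays compared. Correlations between list scores across arrays were given permutation p-values, exact for 6 arrays, and adjusted over the 28 relations computed.

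Results were recomputed under other settings: a fit of only the 12 arrays of each comparison, trend and robust moderation, array weights, dim probe sets left out, a floor at the 25th percentile, quantile normalisation, centring on the array median, the title number as a block or as a subset (up to 120 or above it), neutrophil and mammary secretory scores as covariates, an adjusted p under 0.01, a 2-fold minimum, genes in place of probe sets, the mean of all probe sets of a gene, an estimated correlation, and each array left out. Trend and robust moderation, array weights and the neutrophil and secretory covariates were run on probe set counts and named genes and not on lists, and the title subsets, the stricter threshold, the 2-fold minimum and genes in place of probe sets on counts alone. The estimated correlation was run on lists alone, and the mean of all probe sets on lists and named genes. For genes in place of probe sets limma was fitted again to the 9155 genes, while the gene counts of the results adjust the p-values of the fit to all probe sets over genes. The 4 alternatives added after the data were seen were scaling to the hybridisation controls with dim probe sets left out, the GAPDH control difference as a covariate, leaving out healthy 3 and endometritis 3 together, and macrophage and T cell scores as covariates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with tables handled in pandas 2.3.3.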

Results

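RNA was measured in cells from the milk of 18 cows, 6 healthy, 6 with mastitis and 6 with endometritis, with 1 expression array per cow. Milk somatic cells are the cells that can be spun out of milk: macrophages, lymphocytes, neutrophils and epithelial cells shed from the udder. Mastitis is an inflammation of the udder, most often after bacteria enter the teat. Endometritis is an inflammation of the lining of the uterus after calving, a disease outside the udder. The healthy cows had fewer than 100000 cells per ml of milk and showed no clinical sign of disease. Most of them were sampled 10 to 100 days after calving, while the diseased cows were sampled 10 to 220 days after calving, so stage of lactation can differ between the groups. The labels give lactations 1 to 8 for every group. They give an age of 2 to 4 years for the healthy cows and none for the diseased cows, so age can differ as well. An age of at most 4 years cannot hold together with 8 lactations, so the labels of the healthy cows are in doubt here. Each group held separate animals, so the p-values of limma and of the permutation tests below measure the spread between cows. Those of camera at its preset correlation do not. They rest on the spread over genes, which are treated there as nearly independent. The number of arrays, 6 per group, limits the precision of every value. All values are on the log2 scale, where a difference of 1 is a 2-fold difference, and errors are standard errors (SE) from the fit unless they are named as SD.

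The mastitis arrays stood apart from the others. On the first principal component, which held 57.2% of the variance, mastitis arrays averaged 80.68 ± 21.12 (SD, n = 6) and healthy arrays -47.63 ± 31.43, with an exact two-sided permutation p of 0.00216, the smallest that 6 against 6 can give (0.013 after adjustment over 18 tests of array measures). Endometritis arrays averaged -33.05 ± 35.66 on the same axis, and their difference from healthy did not pass (exact permutation p = 0.448, adjusted 0.576). The median correlation across probe sets was 0.946 between healthy arrays, 0.94 between healthy and endometritis arrays and 0.834 between healthy and mastitis arrays. The distance of arrays from the centre of their own group did not differ between mastitis and healthy, endometritis and healthy, or mastitis and endometritis (exact permutation p = 0.807, 0.277 and 0.297, each two-sided).

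**Figure D1:**
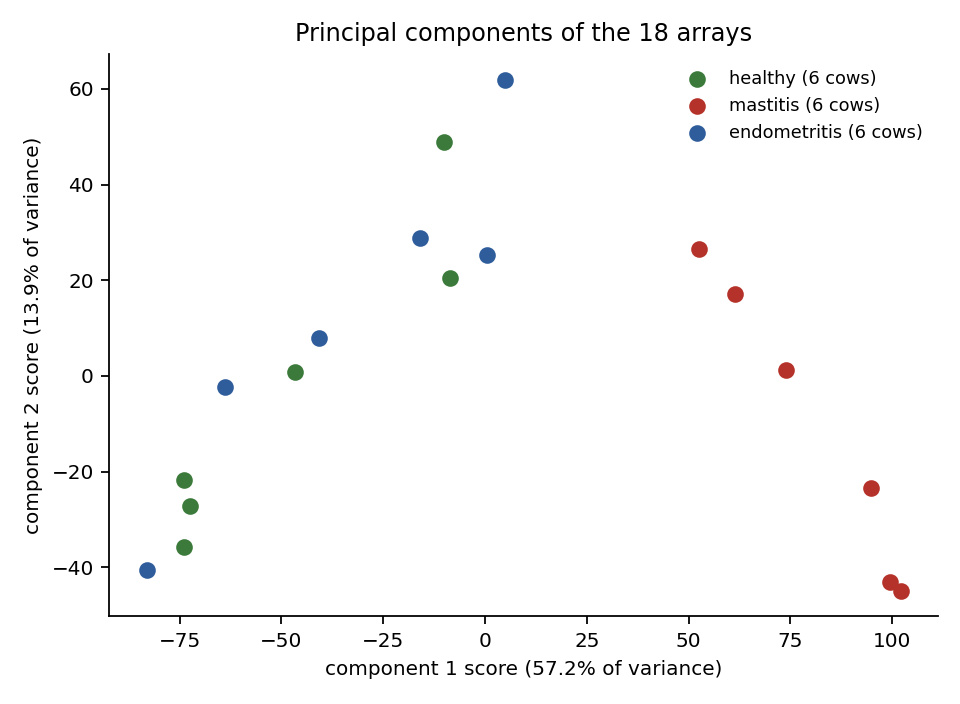
Principal component scores of the 18 arrays, with component 1 (57.2% of the variance) on the horizontal axis and component 2 (13.9%) on the vertical axis, 1 dot per cow and 1 colour per group. The 6 mastitis arrays lie to the right of the 12 other arrays, while healthy and endometritis arrays overlap.

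The first comparison asked how milk cells from udders with mastitis differ from milk cells of healthy udders. Many neutrophil genes and some inflammatory genes were higher in mastitis, and many genes for making milk were lower. CXCR1, a neutrophil receptor for interleukin 8, rose by 5.51 ± 0.84 (n = 6 and 6), a 45.5-fold increase with an adjusted p of 0.000365. S100A9, a calcium-binding protein abundant in neutrophils, rose by 5.48 ± 0.77, and PTX3, a soluble pattern recognition protein, rose by 5.37 ± 0.84. ELF5, a transcription factor of the milk-secreting epithelium, fell by 8.00 ± 0.92, or 256-fold (adjusted p = 4.95e-05), and LALBA, the alpha-lactalbumin subunit of lactose synthase, fell by 6.15 ± 0.73. LALBA, CSN3 and CSN2 read 13.37, 13.89 and 13.33 on healthy arrays, near the highest value of 14.2, so their falls here and against endometritis can be larger than printed.

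The 15 genes chosen for the largest rise ran from G0S2 at 4.59 to CXCR1 at 5.51, and each was above the healthy mean on all 6 mastitis arrays, as the rule for naming them requires. They included THBD at 5.49, PSTPIP2 at 5.33, the macrophage growth factor CSF1 at 5.23, inducible nitric oxide synthase NOS2 at 4.99, the interferon-induced GTPase GBP1 at 4.91 and the phagocyte oxidase subunit NCF1 at 4.89. CSF1 passed at 1 of its 2 probe sets and NOS2 at 2 of 4. The 10 genes chosen for the largest fall ran from GPAM at -6.15 to ELF5 at -8.00. Among them were DNAJC12 at -7.51, the milk fat globule protein BTN1A1 at -7.27, the mucin-like milk protein GLYCAM1 at -6.77, the transporter ABCG2 at -6.49 (1 of 2 probe sets), the fatty acid binding protein FABP3 at -6.33 and stearoyl-CoA desaturase SCD at -6.18.

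Across the array, limma's two-sided test called 2443 probe sets higher and 2246 lower in mastitis, 19.5% of the 24016 tested, and 1614 and 1361 of these differed at least 2-fold. At 1 representative probe set per gene, with p adjusted over the 9155 genes, 1124 genes were higher and 1596 lower. An unadjusted p under 0.05 was reached by 7079 probe sets, against 1201 expected by chance. With the neutrophil and mammary secretory scores as covariates, which themselves part the groups and so take up most of the difference, the counts were 6 higher and 60 lower, of which 1 and 2 were among those called without them, and with the GAPDH control difference as a covariate they were 856 and 572. Fits on subsets by the number in the sample titles gave 78 and 41 up to 120 and 1459 and 888 above it, and arrays scaled to the hybridisation controls with dim probe sets left out gave 752 lower, against 2621 with dim probe sets left out alone.

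Among the 15 measured neutrophil markers, 10 rose, 0 fell and 5 did not pass (11 rose and 0 fell when adjusted over the list alone). Their median difference was 3.68 (camera adjusted p = 1.18e-09, adjusted p = 0.093 with an estimated correlation), and all 15 lay above 0. VNN2 rose by 4.88, NCF4 by 3.10 and S100A8 by 4.56 ± 0.67. Of the 22 measured mammary secretory genes, 0 rose, 16 fell and 6 did not pass (0 rose and 17 fell when adjusted over the list alone). The secretory median was -4.61 (camera adjusted p = 2.47e-10, adjusted p = 0.115 with an estimated correlation). The casein CSN3 fell by 5.64, the casein CSN2 fell by 5.25 (2 of 3 probe sets), and PAEP, beta-lactoglobulin, fell by 5.16. Epithelial structure genes gave 1 higher, 8 lower and 11 not passing of 20 (1 and 10 adjusted over the list alone). The epithelial median was -0.33 (camera adjusted p = 0.0115, adjusted p = 0.284 with an estimated correlation). KRT19 fell by 5.67, EPCAM fell by 3.87 and CLDN7 fell by 2.90, while the laminin chain LAMB3, chosen after its value was seen and at background in healthy, was at least 2.35-fold higher. Of these lists' members, 10 of the 15 neutrophil, 19 of the 22 secretory and 12 of the 20 epithelial genes were above the array median of 2.55 on all healthy arrays.

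Markers of other cell types gave smaller differences. Of 18 macrophage markers, 0 rose, 1 fell and 17 did not pass (0 rose and 1 fell when adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.563, adjusted p = 0.886 with an estimated correlation). The member that fell was LPL, lipoprotein lipase, which udder epithelium also makes, at -2.54; CD68 was 1.94 higher (adjusted p = 0.0986) and did not pass. None of the 17 T cell markers passed in limma (0 adjusted over the list alone), with a median of -0.01 (camera adjusted p = 0.775, adjusted p = 0.951 with an estimated correlation). For this list the median and the mean (-0.20) were below 0 while camera's direction was upward. NK and cytotoxic markers had 2 of 13 members higher (1 adjusted over the list alone), GNLY, a cytolytic granule protein, at 3.61 and NCR1, at background in healthy and at least 1.04-fold higher, with a median of 0.17 (camera adjusted p = 0.0477, adjusted p = 0.421 with an estimated correlation). That call was lost in 9 of the 18 fits that left out 1 array (adjusted p 0.0503 to 0.118 there) and did not pass in the fit of 12 arrays, with dim probe sets left out, without or with scaling to the hybridisation controls, with median centring, with the title number as a block or with the GAPDH covariate (adjusted p = 0.0518, 0.143, 0.138, 0.0732, 0.062 and 0.121). NCR1 was lost in 14 of the 18 fits that left out 1 array (adjusted p 0.0535 to 0.0992 there). B and plasma cell markers had a median of 0.05 (camera adjusted p = 0.514, adjusted p = 0.707 with an estimated correlation), and BLK, the member of 9 that passed, rose by 0.53 (0 adjusted over the list alone). Its call was lost in 8 of the 18 fits that left out 1 array (adjusted p 0.0546 to 0.0784 there). The 9 erythroid genes had a median of 0.04 (camera adjusted p = 0.29, adjusted p = 0.337 with an estimated correlation), and 0 passed in limma.

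Control probe sets moved with the groups as well. The spiked-in dap poly-A controls, added in a fixed amount, read 6.70 ± 0.40 (SD, n = 6) on mastitis arrays and 8.16 ± 0.87 on healthy arrays (exact two-sided permutation p = 0.00216, adjusted 0.013). The difference between the 3′ and 5′ GAPDH control probe sets, a sign of RNA integrity, was 0.39 ± 0.23 in mastitis and 0.88 ± 0.40 in healthy (exact permutation p = 0.0195, adjusted 0.0877). Endometritis arrays lay between them, at 7.68 ± 0.84 for dap and 0.58 ± 0.25 for GAPDH. When arrays were scaled to the hybridisation controls, the median difference of the 12321 probe sets left without dim ones went from -0.01 to 0.33 in mastitis against healthy and from 0.03 to 0.23 in endometritis against healthy. The differences in the hybridisation controls themselves did not pass (exact permutation p = 0.221 and 0.567), and without healthy 3 they went from -0.35 and -0.20 to -0.14 and 0.000955. The second difference also shrank without endometritis 5 (-0.0543) or endometritis 6 (-0.0607), so these shifts depend on single arrays.

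Some signalling genes of inflammation rose. Of 22 inflammatory cytokines and chemokines, 7 rose, 0 fell and 15 did not pass (8 rose and 0 fell when adjusted over the list alone), with a median of 0.99 (camera adjusted p = 0.000104, adjusted p = 0.203 with an estimated correlation). CXCL8, the neutrophil attractant interleukin 8, rose by 1.80 ± 0.45, IL15 by 1.91 and CXCL10 by 2.95. With the GAPDH difference as a covariate CXCL8 (adjusted p = 0.154) and CXCL10 (adjusted p = 0.0621) no longer passed, among 20 of the 136 named genes of this comparison that lost their call so. IL1B was 2.33 higher (adjusted p = 0.122), IL6, at background in healthy, at least 1.98-fold higher (adjusted p = 0.0651) and TNF 0.01 higher (adjusted p = 1), and none of these passed. IL6 passed under 4 other settings, such as array weights (adjusted p = 0.0283), and without mastitis 1 (adjusted p = 0.0293). The 14 anti-inflammatory mediators had 10 higher, 0 lower and 4 not passing (10 and 1 adjusted over the list alone), and their median was 2.29 (camera adjusted p = 4.61e-07, adjusted p = 0.093 with an estimated correlation). TNIP1, a brake on NF-kappaB, rose by 3.57 and the cytokine signalling inhibitor SOCS3 by 2.33. In the Toll-like receptor and NF-kappaB list, 12 rose, 0 fell and 11 did not pass (14 rose and 0 fell when adjusted over the list alone). The median there was 0.76 (camera adjusted p = 1.87e-08, adjusted p = 0.093 with an estimated correlation). TLR4, the receptor for bacterial lipopolysaccharide, rose by 4.42 ± 0.69, TLR2 by 3.29 and IKBKB by 2.93, while CD14 was 1.31 higher without passing (adjusted p = 0.21, 1 of its 2 probe sets passed).

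Many interferon response genes rose. Of 24, 16 rose, 0 fell and 8 did not pass (19 rose and 0 fell when adjusted over the list alone), with a median of 2.40 (camera adjusted p = 9.52e-12, adjusted p = 0.124 with an estimated correlation). IRF9, a part of the interferon-activated transcription complex, rose by 3.64 ± 0.34, the interferon regulator IRF7 by 2.83 (2 of 3 probe sets) and PARP14 by 3.21. MHC class I presentation genes gave 10 of 16 higher (13 adjusted over the list alone) and 0 lower, with a median of 1.59 (camera adjusted p = 2.31e-10, adjusted p = 0.093 with an estimated correlation). The peptide transporter TAP1 rose by 3.29 and the immunoproteasome subunit PSMB9 by 2.65. MHC class II presentation genes gave 4 of 17 higher (4 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 0.00361, adjusted p = 0.329 with an estimated correlation), among them BOLA-DMA at 2.00 and CD80 at 1.16. Among 18 complement genes, 5 rose, 0 fell and 13 did not pass (6 rose and 0 fell when adjusted over the list alone). The complement median was 0.13 (camera adjusted p = 0.00195, adjusted p = 0.131 with an estimated correlation). CD55, which protects cells from complement, rose by 4.02 and factor B, CFB, by 3.07. Antimicrobial and acute phase genes split, with 3 of 24 higher and 2 lower (4 and 2 adjusted over the list alone) and a median of 0.12 (camera adjusted p = 0.0462, adjusted p = 0.329 with an estimated correlation). DEFB10, a beta-defensin, rose by 3.95 and SAA3, mammary serum amyloid, by 1.95, while lactoferrin, LTF, fell by 2.05 (1 of 2 probe sets) and the cathelicidin CATHL5, chosen after its value was seen, fell by 0.62. HP, haptoglobin, was 1.54 higher and did not pass (adjusted p = 0.158). The call of this list was lost in 5 of the 18 fits that left out 1 array (adjusted p 0.0536 to 0.0947 there), that of SAA3 in 7 and that of LTF in 3, and the list did not pass in the fit of 12 arrays, with dim probe sets left out, without or with scaling to the hybridisation controls, with median centring, with the GAPDH covariate or with macrophage and T cell scores (adjusted p = 0.0664, 0.106, 0.0924, 0.0544, 0.0558 and 0.0667).

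Phagocyte oxidase and oxidative defence genes moved in both directions. Of 27, 10 rose, 4 fell and 13 did not pass (13 rose and 5 fell when adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.00385, adjusted p = 0.337 with an estimated correlation). The oxidase subunits NCF1 and NCF4 rose by 4.89 and 3.10, and superoxide dismutase SOD2, chosen after its value was seen, by 2.66. The members that fell were SOD1, at -3.25, and, chosen after their values were seen, CAT, GPX4 at -1.32 and NQO1 at -0.99. With the GAPDH difference as a covariate the list did not pass (adjusted p = 0.0694), as the NK and antimicrobial lists above did not, and no other list called in this comparison lost its call under a setting run on lists, except with an estimated correlation. Eicosanoid genes split evenly, with 4 higher and 4 lower of 17 (4 and 4 adjusted over the list alone), and a median near 0 (mean -0.09, camera direction upward with adjusted p = 0.583, and adjusted p = 0.607 with an estimated correlation). PTGER4, a prostaglandin E2 receptor, rose by 2.58 and the leukotriene receptor LTB4R by 1.74, while ALOX15, a lipoxygenase at background on all mastitis arrays, was at least 41.6-fold lower. Leukocyte adhesion and migration genes gave 9 of 19 higher (9 adjusted over the list alone) and 0 lower, with a median of 1.36 (camera adjusted p = 3.47e-06, adjusted p = 0.106 with an estimated correlation), among them ICAM3 at 3.96 and ICAM1 at 3.68. In the matrix remodelling list, 3 rose, 1 fell and 19 did not pass (2 rose and 1 fell when adjusted over the list alone). The matrix median was 0.01 (camera adjusted p = 0.239, adjusted p = 0.466 with an estimated correlation), with the protease inhibitor TIMP1 at 3.17, VCAN at 2.79, PLAUR at 2.48 and TIMP3 at -1.44. PLAUR was lost in 12 of the 18 fits that left out 1 array (adjusted p 0.0547 to 0.11 there).

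Most genes of oxidative phosphorylation and the ribosome fell, and some glycolysis genes rose. Of 43 nuclear genes of oxidative phosphorylation, 0 rose, 34 fell and 9 did not pass (1 rose and 37 fell when adjusted over the list alone). The oxidative phosphorylation median was -1.24 (camera adjusted p = 4.72e-14, adjusted p = 0.203 with an estimated correlation), and UQCRB, a subunit of respiratory complex III, fell by 2.05 ± 0.24 (1 of 2 probe sets) and NDUFB3 of complex I fell by 1.93. Among 48 ribosomal proteins, 1 rose, 40 fell and 7 did not pass (1 rose and 44 fell when adjusted over the list alone). The ribosomal median was -1.18 (camera adjusted p = 2.46e-13, adjusted p = 0.266 with an estimated correlation). RPLP0 fell by 1.88 and RPL37, chosen after its value was seen, rose from background in healthy. Both falls were uneven: on mastitis 1, 2 and 4 the ribosomal score was -1.46, -1.38 and -1.20 and the oxidative phosphorylation score -1.29, -1.15 and -1.14. On mastitis 3, 5 and 6 they were -0.18, 0.06 and -0.13, and -0.11, 0.04 and -0.55. Over the 6 mastitis arrays the ribosomal score had r = -0.909 with the neutrophil score (exact permutation p = 0.0278, adjusted 0.194). Milk fat and cholesterol synthesis genes gave 2 higher and 10 lower of 29 (2 and 13 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.000351, adjusted p = 0.203 with an estimated correlation). Fatty acid synthase, FASN, fell by 5.62 and ACSS2 fell by 5.73, while the triglyceride enzymes DGAT2 and, chosen after its value was seen, DGAT1 rose by 3.54 and 1.02. Of 28 glycolysis and hypoxia genes, 13 rose, 1 fell and 14 did not pass (18 rose and 2 fell when adjusted over the list alone). The glycolysis median was 1.44 (camera adjusted p = 1.07e-06, adjusted p = 0.203 with an estimated correlation). The lactate transporter SLC16A3 rose by 3.89 (1 of 3 probe sets), VEGFA by 3.12 and the glucose transporter SLC2A1 by 1.97, while ALDOC, chosen after its value was seen, fell by 1.76.

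Some stress and survival genes rose in mastitis too. Apoptosis and survival genes gave 10 of 21 higher and 0 lower (11 and 1 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 1.96e-06, adjusted p = 0.093 with an estimated correlation). The death receptor FAS rose by 3.45 and the survival factor BCL2L1 by 1.13. Immediate early and heat shock genes, which also respond to handling of cells, gave 12 of 25 higher (14 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 3.06e-07, adjusted p = 0.159 with an estimated correlation), JUN at 3.59 and DDIT3 at 2.91. Glucocorticoid response genes gave 7 of 12 higher and 0 lower (7 and 1 adjusted over the list alone), with a median of 1.35 (camera adjusted p = 0.0133, adjusted p = 0.203 with an estimated correlation) and DDIT4 at 4.46. Of 26 cell cycle genes, 1 rose, 0 fell and 25 did not pass (1 rose and 0 fell when adjusted over the list alone). The cell cycle median was -0.11 (camera adjusted p = 0.976, adjusted p = 0.993 with an estimated correlation), its mean -0.06 and its camera direction upward, and the member that passed was NUSAP1 at 2.30. In all, camera called 16 lists higher and 5 lower of 28, fry called 20, and none passed with an estimated correlation, where the lowest adjusted p was 0.093. Lists overlap in 9 genes, each held by 2 of them.

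**Figure D2:**
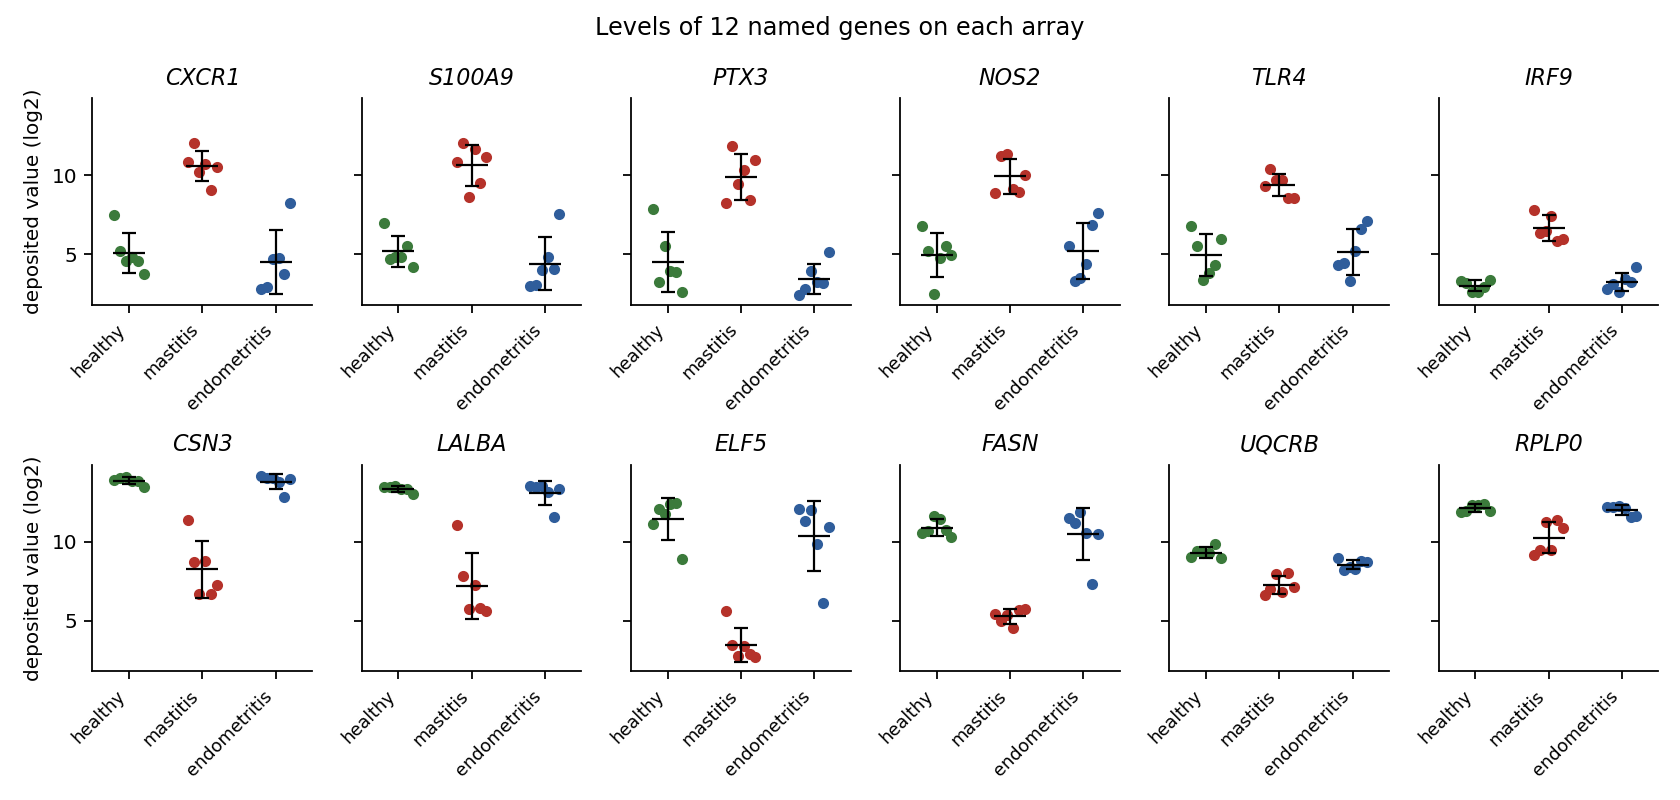
Log2 values of 12 named genes on the vertical axis for each group on the horizontal axis, with 1 dot per array and bars for the mean ± SD of 6 arrays. Mastitis arrays are higher for CXCR1, S100A9 and PTX3 and lower for CSN3, LALBA and ELF5, and the ranges of healthy and endometritis arrays overlap for 11 of the 12 genes, all but UQCRB.

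**Figure D3:**
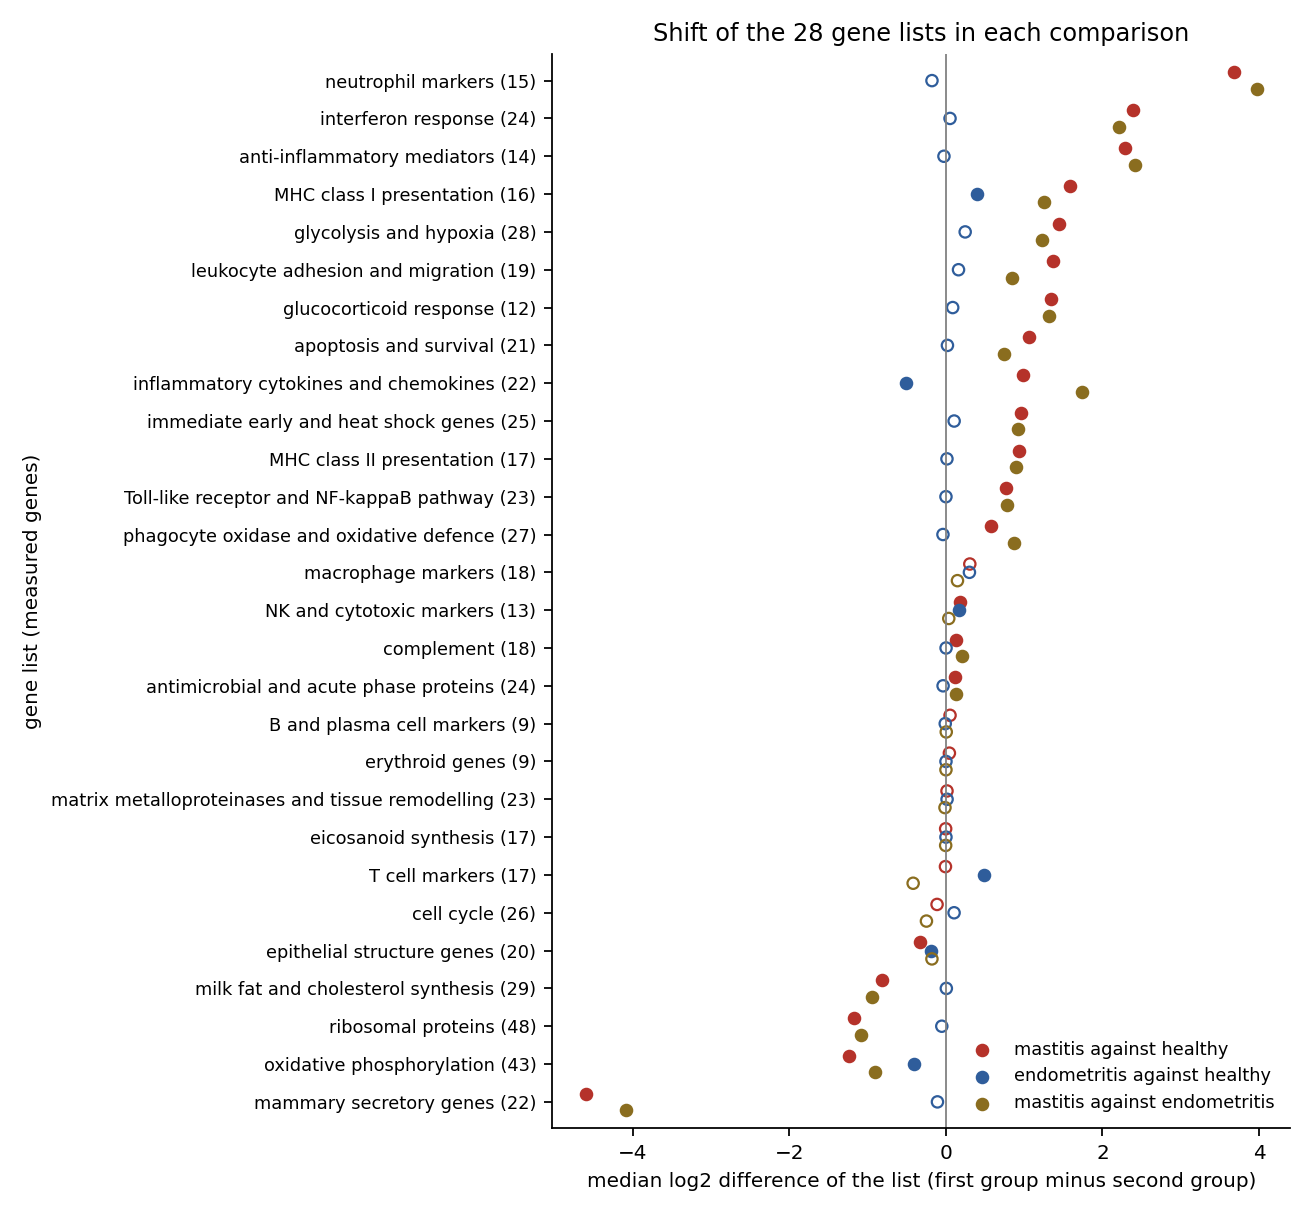
Median log2 difference of each of the 28 gene lists on the horizontal axis, 1 line per list and 1 colour per comparison, with circles filled where camera called the list with its preset correlation and open where it did not. Medians of mastitis against healthy run from -4.61 for mammary secretory genes to 3.68 for neutrophil markers, and no circle would be filled with an estimated correlation.

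The second comparison asked whether disease of the uterus can be read in milk cells. No single gene passed when p was adjusted over all probe sets, and 1, ASB11, was lower when it was adjusted over the 9155 genes. ASB11, an ankyrin repeat protein of a ubiquitin ligase, had the smallest adjusted p over all probe sets, 0.0566: it read 3.72 ± 0.06 (SD, n = 6) in endometritis and 7.45 ± 1.56 in healthy, a difference of -3.73 ± 0.52, and was below the healthy mean on 6 of 6 arrays. It passed without healthy 6 (adjusted p = 4.48e-06) and under 6 other settings, and over all alternatives its adjusted p ran from 4.48e-06 to 0.518. The genes with the next smallest p were CHCHD10 at -1.34 (adjusted p = 0.572), POLR2J at -0.66, CRYAB, a small heat shock protein, at -1.77 and RRAD at -1.93 among those lower, and CTR9 at 0.84 (adjusted p = 0.596), DNAJC9 at 0.17, GTPBP4 at 0.72 and the lipid regulator SREBF1 at 0.76 among those higher. KLRB1 belongs to them by its p, but it is at background in healthy, and its lower bound of 0.971-fold does not settle whether it rose.

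In limma 0 probe sets were higher and 0 lower at an adjusted p under 0.05, with 1047 at an unadjusted p under 0.05 against 1201 expected by chance. Trend and robust moderation, and separately array weights, called 0 higher and 1 lower. With only arrays whose title number is up to 120, a fit that holds a single endometritis array, 516 were higher and 15 lower. On data simulated for this comparison, limma called 86% of 50 probe sets moved by 2 log2 units and 42% of those moved by 1. All of these had a mean above the median of 2.55. Dim probe sets were not moved, so their recovery was not measured and can be lower. Among milk genes LALBA differed by -0.26 ± 0.73, CSN3 by -0.07 ± 0.62 and CSN2 by -0.19 ± 0.66. These read 13.37, 13.89 and 13.33 on healthy arrays, near the highest value of 14.2, where a difference can be hidden. Endometritis 5 read 11.58 for LALBA and 12.85 for CSN3. The other endometritis arrays read 13.18 to 13.54 and 13.80 to 14.18, so the sign of both differences rests on 1 cow. The dimmer ELF5 and MFGE8 differed by -1.08 ± 0.92 and -0.95 ± 0.78. ELF5 read 6.13 on endometritis 5 and 9.85 to 12.08 on the other endometritis arrays, so its difference rests largely on 1 cow. Among inflammatory genes, CXCL8 differed by -0.33, IL1B by -1.21, TNF by -0.59, TLR2 by 0.46, TLR4 by 0.18 and CD14 by 0.32, and IL6, at background in healthy, was at least 1.05-fold higher. S100A8 and S100A9 differed by -0.90 and -0.77, LTF by -1.01, HP by -1.10 and SAA3 by -0.09, and none of these passed.

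Of the 28 lists, camera called 3 higher and 3 lower in endometritis, while fry called 0 and no list passed with an estimated correlation. Oxidative phosphorylation genes were lower, with a median of -0.41 (camera adjusted p = 1.2e-10, adjusted p = 0.999 with an estimated correlation) and 39 of 43 members below 0. NDUFA1 of complex I read -0.63 ± 0.19, UQCRB -0.76 ± 0.24 and NDUFA6 -0.60 ± 0.17, and no member passed alone. The score of this list, the mean of its members on each array, differed by -0.38 from healthy and lay below the healthy mean on 6 of 6 endometritis arrays (exact two-sided permutation p = 0.0108, adjusted 0.303 over 28 lists). MHC class I presentation genes were higher, with a median of 0.40 (camera adjusted p = 0.000101, adjusted p = 0.999 with an estimated correlation), CALR at 0.80, TAPBP at 0.59 and PSMB8 at 0.58. This call was lost with the GAPDH difference as a covariate (adjusted p = 0.112). NK and cytotoxic markers had a median of 0.16 (camera adjusted p = 0.00519, adjusted p = 0.999 with an estimated correlation), with CTSW at 1.39 and KLRK1 at 0.75. T cell markers had a median of 0.48 (camera adjusted p = 0.0393, adjusted p = 0.999 with an estimated correlation), with CD96 at 1.05 and CD3G at 0.93. The T cell score was above the healthy mean of -0.08 on 3 of 6 endometritis arrays, with endometritis 2 and 4 at 1.60 and 1.98 and the others from -0.52 to -0.07. Scores of the 5 lists called besides oxidative phosphorylation did not pass (exact permutation p = 0.145 for MHC class I, 0.24 for NK, 0.4 for T cell, 0.312 for epithelial and 0.288 for cytokine genes). The NK list without 1 of the arrays (adjusted p = 0.0707 without endometritis 4) and the NK list with the macrophage and T cell scores as covariates (adjusted p = 0.114) did not pass.

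Epithelial structure genes were lower in endometritis, with a median of -0.19 (camera adjusted p = 0.0393, adjusted p = 0.999 with an estimated correlation), and so were inflammatory cytokines and chemokines, with a median of -0.51 (camera adjusted p = 0.0472, adjusted p = 0.999 with an estimated correlation). The chemokines CCL4 and CCL3 read -1.78 and -1.26, and PTX3 -1.07. These calls depended on single arrays and on the settings: T cell markers were lost in 6 of the 18 fits that left out 1 array (adjusted p 0.051 to 0.598 there), epithelial structure genes in 8 (0.0503 to 0.372) and cytokines in 11 (0.0501 to 0.358). Epithelial structure genes also did not pass in the fit of 12 arrays, with quantile normalisation, with the GAPDH covariate or with macrophage and T cell scores (adjusted p = 0.123, 0.0738, 0.425 and 0.207), nor T cell markers with the GAPDH covariate (0.104). Cytokines did not pass in the fit of 12 arrays, with quantile normalisation, with the mean of all probe sets, without healthy 3 and endometritis 3, or with macrophage and T cell scores (adjusted p = 0.147, 0.0621, 0.0807, 0.164 and 0.106). The other 22 lists were not called, with medians from -0.18 for neutrophil markers to 0.30 for macrophage markers and adjusted p values from 0.0911 for leukocyte adhesion to 0.999 for apoptosis. Mammary secretory genes had a median of -0.11 (camera adjusted p = 0.467) and ribosomal proteins of -0.05 (0.467). The median and camera's direction differed for glucocorticoid response genes (median 0.09, direction downward), and the mean and the direction for this list, B and plasma cell markers, Toll-like receptor, MHC class II presentation, milk fat and eicosanoid genes.

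The third comparison set mastitis against endometritis, which also tests whether the differences of each disease from healthy differ from each other. Cells of the inflamed udder had more RNA of neutrophil genes and less of milk genes. PTX3 rose by 6.44 ± 0.84 (n = 6 and 6, adjusted p = 0.00017), S100A9 by 6.25 ± 0.77, CXCR1 by 6.06 ± 0.84 and S100A8 by 5.47 ± 0.67. ELF5 fell by 6.92 ± 0.92, BTN1A1 fell by 6.49, GLYCAM1 fell by 6.34, LALBA fell by 5.89 and CSN3 fell by 5.57. IL1B, which did not pass against healthy, rose by 3.54 ± 0.99 (adjusted p = 0.0238), and HP rose by 2.64 (adjusted p = 0.019). The IL1B call was lost in 4 of the 18 fits that left out 1 array (adjusted p 0.0507 to 0.0602 there) and did not pass in a fit of the 12 arrays alone (adjusted p = 0.056). LTF at -1.04, TNF at 0.60, IL6 at 0.92 and CD14 at 0.99 did not pass.

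In this comparison 1919 probe sets were higher and 1574 lower, 14.5% of those tested, with 6186 at an unadjusted p under 0.05, and 930 and 1160 genes at their representative probe set, adjusted over genes. Of the probe sets called against endometritis or healthy, 3054 were called in both, all in the same direction, which the mastitis arrays shared by both comparisons favour. Another 1635 were called only against healthy and 439 only against endometritis. With the neutrophil and mammary secretory scores as covariates 17 were higher and 141 lower, sharing 5 and 2 with the counts above. With title numbers up to 120 the counts were 109 and 704, with those above 120 859 were lower, and with arrays scaled to the hybridisation controls and dim probe sets left out the counts were 1251 and 583, against 2181 and 2084 with dim probe sets left out alone.

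Camera called 15 lists higher and 4 lower in mastitis than in endometritis, fry called 20, and none passed with an estimated correlation (lowest adjusted p = 0.0734). Of 15 neutrophil markers, 10 rose, 0 fell and 5 did not pass (10 rose and 0 fell when adjusted over the list alone), with a median of 3.97 (camera adjusted p = 2.07e-11, adjusted p = 0.0734 with an estimated correlation). Of 22 mammary secretory genes, 0 rose, 17 fell and 5 did not pass (0 rose and 17 fell when adjusted over the list alone), with a median of -4.09 (camera adjusted p = 2.5e-11, adjusted p = 0.0961 with an estimated correlation). In the cytokine list 10 of 22 rose (13 adjusted over the list alone), with CCL20 at 2.71 and a median of 1.74 (camera adjusted p = 1e-07, adjusted p = 0.108 with an estimated correlation). Interferon response genes had 15 of 24 higher (18 adjusted over the list alone) and a median of 2.22 (camera adjusted p = 1.47e-13, adjusted p = 0.0961 with an estimated correlation), with IRF9 at 3.41. Oxidative phosphorylation genes had 24 of 43 lower (35 adjusted over the list alone) and a median of -0.90 (camera adjusted p = 2.73e-10, adjusted p = 0.233 with an estimated correlation), with NDUFA4 at -2.14. Ribosomal proteins had 38 of 48 lower (44 adjusted over the list alone) and a median of -1.09 (camera adjusted p = 3.44e-14, adjusted p = 0.233 with an estimated correlation). The dap controls read lower in mastitis than in endometritis (exact permutation p = 0.0325, adjusted 0.117).

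Further calls upward were anti-inflammatory mediators at a median of 2.42 (camera adjusted p = 1.56e-08, adjusted p = 0.0734 with an estimated correlation), Toll-like receptor genes at a median of 0.78 (camera adjusted p = 8.92e-10, adjusted p = 0.0734 with an estimated correlation), MHC class I at a median of 1.25 (camera adjusted p = 1.55e-08, adjusted p = 0.0961 with an estimated correlation) and apoptosis at a median of 0.74 (camera adjusted p = 2.84e-07, adjusted p = 0.0734 with an estimated correlation). TNIP1 rose by 3.70, NFKBIE by 2.37, TAPBPL by 2.51 and FADD, an adaptor of death receptors, by 0.74. Leukocyte adhesion, glycolysis, immediate early and phagocyte oxidase genes were called upward with medians of 0.85, 1.23, 0.93 and 0.86 (adjusted p = 0.112, 0.192, 0.136 and 0.269 with an estimated correlation). SOD2 rose by 3.15 and SOD1 fell by 3.27, and ALDOC fell by 1.78. Complement, MHC class II, glucocorticoid response and antimicrobial genes were called upward with medians of 0.20, 0.90, 1.32 and 0.13 (adjusted p = 0.108, 0.253, 0.136 and 0.192 with an estimated correlation). CFB rose by 3.49 and TAP, an antimicrobial peptide of epithelium, by 2.04. Milk fat and cholesterol genes were called downward with a median of -0.95 (camera adjusted p = 4.74e-05, adjusted p = 0.136 with an estimated correlation). FASN fell by 5.21 while DGAT2 rose by 3.71. Epithelial structure genes, with a median of -0.18, were not called (adjusted p = 0.0833), though KRT19 fell by 4.71 and LAMB3, at background in endometritis, was at least 2.35-fold higher. Macrophage, T cell, NK, B cell, erythroid, eicosanoid, cell cycle and matrix lists were not called either. LPL fell by 2.82, TCF7, a T cell transcription factor, fell by 2.74 (adjusted p = 0.0394), LTA4H fell by 1.38, and ALOX15 was at least 30-fold lower. The TCF7 call was lost in 8 of the 18 fits that left out 1 array (adjusted p 0.0533 to 0.091 there). The median and camera's direction differed for the eicosanoid, matrix and erythroid lists, and the mean and the direction for the macrophage, B cell, erythroid and eicosanoid lists.

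Both diseases were set against the same healthy cows, and their differences from healthy correlated across probe sets at r = 0.433, where probe sets are not independent replicates. Data simulated with 3 unchanged groups that share their controls gave a median r of 0.558, from -0.0254 to 0.851 for the central 95% of simulations, and 67% of simulated values were at or above the observed one. The observed covariance was 0.0882, against a simulated mean of 0.0285 and an upper limit of 0.0766 for the central 95% of simulations. With the healthy cows split so that each disease had its own 3 controls, the median r over 20 assignments was 0.329, from -0.283 to 0.459. The simulated groups held no disease difference, while mastitis differed widely from healthy, which lowers any r that comes from shared controls. The simulated and observed r therefore cannot be compared directly, and the comparison of r decides nothing. The observed covariance was above its simulated upper limit, but that limit was also simulated without a mastitis difference. A wide mastitis difference widens the spread of the covariance, so this comparison decides nothing either. With split controls the mean covariance was 0.0624, for which no limit was computed.

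**Figure D4:**
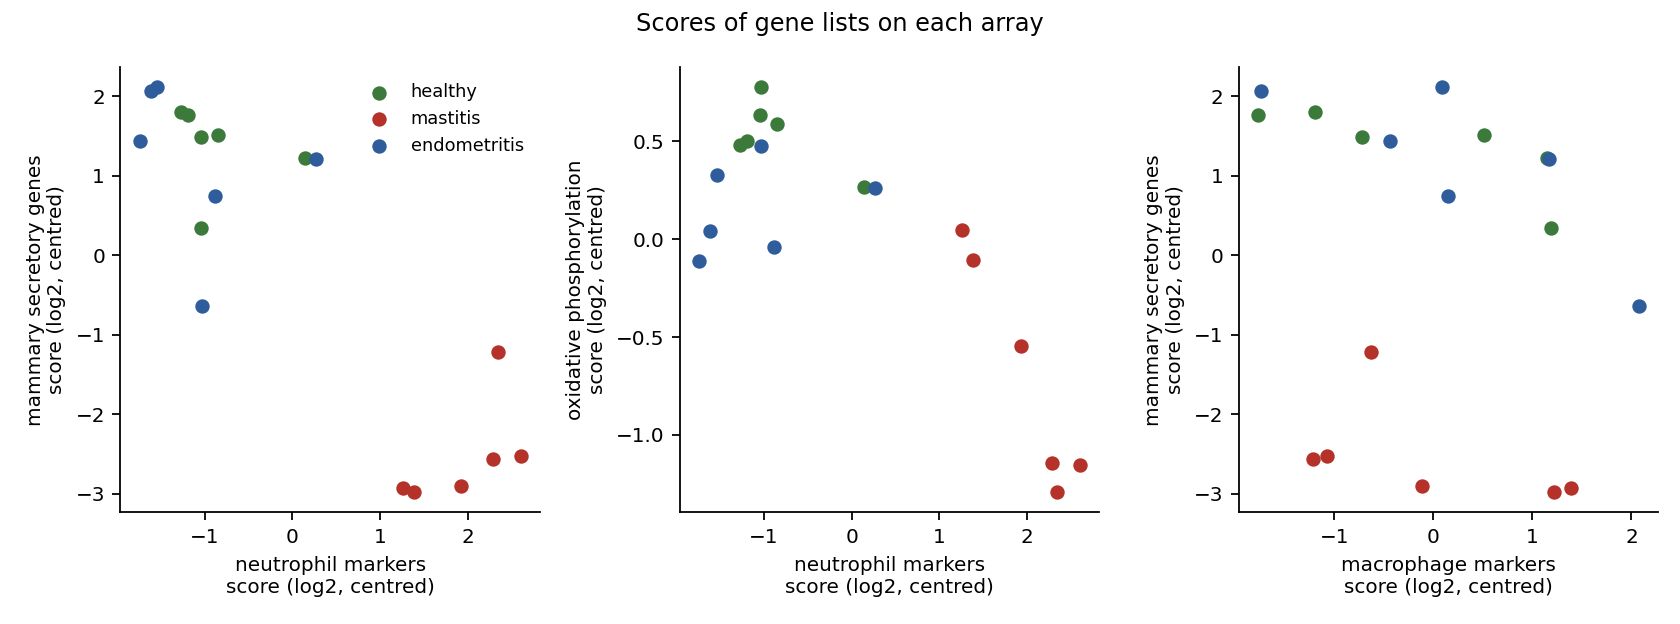
Scores of gene lists per array, the mean over members of log2 values centred on the mean of all arrays, plotted as neutrophil against mammary secretory, neutrophil against oxidative phosphorylation and macrophage against mammary secretory scores, 1 dot per array and 1 colour per group. Mastitis arrays hold the highest neutrophil scores, from 1.26 to 2.61, and healthy arrays lie between -1.27 and 0.14.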

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

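The 8 values below come from a rule fixed before the values were seen, while the 4 tests of the pattern that follows them were chosen after the result was seen. A value is listed where the highest or lowest of 6 arrays of a group lies apart from its nearest neighbour by more of the group's range than the 95% limit of Dixon's test for 6 values allows. Chance gives this in about 1 in 20 groups: 96 groups were tested, 4.8 such values are expected by chance and 8 were found. The neutrophil score of healthy 1 was 0.144, above the next healthy array at -0.85. The eicosanoid score of healthy 6 was -0.267, below the next at 0.03, and its cell cycle score was 0.950, above the next at 0.04. The hybridisation controls of healthy 3 averaged 8.51, above the next at 7.51, and its dap poly-A controls averaged 9.85, above the next at 8.16. The mammary secretory score of mastitis 1 was -1.22, above the next mastitis array at -2.53. The milk fat and cholesterol score of endometritis 5 was -0.438, below the next at 0.30, and its cell cycle score was 1.39, above the next at 0.14.

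Mammary secretory genes were lower in mastitis, with a median of -4.61. A lower share of secretory cells alone would raise the scores of all other cell types alike, but the neutrophil score changed by 2.78 ± 0.79 (SE) more than the macrophage score (exact permutation p = 0.013). Dilution of all other cells by neutrophils alone would lower macrophage markers as far, but the macrophage score changed by 3.94 ± 0.95 (SE) more than the secretory score (exact permutation p = 0.00433). More degraded RNA would raise the GAPDH difference, which was -0.49 ± 0.19 (SE) from healthy (exact permutation p = 0.0195, adjusted 0.0877 over 18 tests of array measures). Scaling by the authors would move other genes of the same level as far, but the secretory score changed by -3.98 ± 0.44 (SE) relative to the genes nearest in mean level (exact permutation p = 0.00216). Over all alternatives the adjusted p of this list ran from 8.61e-26 to 0.115, the latter with an estimated correlation. The cell share and scaling tests argue against those explanations as the whole cause. The cell share tests do so only as far as the macrophage score follows macrophages, and its member LPL is also made by udder epithelium. The GAPDH difference went the opposite way to more degraded RNA but did not pass after adjustment, so it argues against that only weakly. A change in several cell types at once, or less RNA of milk genes in each secretory cell during mastitis, may account for the pattern, and neither was tested.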

How the results depend on the processing

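Scaling to the hybridisation controls, the GAPDH covariate, the macrophage and T cell covariates and leaving out healthy 3 and endometritis 3 together were chosen after the data were seen, and all other settings before. The title number as a block, the floor at the 25th percentile and, for probe sets, quantile normalisation and the fit of 12 arrays changed no count by over 1.5 times. The correlation of the disease differences, r = 0.433, stayed within its jackknife standard error of 0.349 under every setting run on it, which is a wide margin. The spread of arrays around their groups, for which no error was computed, did not pass under any setting run on it. For mastitis against healthy its difference ran from -0.028 to 0.0423 with 1 array left out, so its sign was not fixed. Results not passing both with and without a setting were counted as kept. No paired fit was made, because each cow is in 1 group and replicate numbers only count the cows of a group. The title numbers have no stated meaning, and the fit of those up to 120 holds 1 endometritis array, assumed to vary like the others. Leaving out dim probe sets removes 1 list and some named genes, which then have no value. Values pile up at the floor, with the lowest at 2.43, the 25th percentile at 2.43 and the median at 2.55. Differences between dim probe sets are therefore compressed. The cause was not tested for the changes below, except where fewer arrays, a stricter threshold or genes in place of probe sets make it plain.

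For mastitis against healthy, probe sets higher and lower were 78 and 41 with title numbers up to 120 (78 and 33 shared with the 2443 and 2246), 1459 and 888 above 120 (1149 and 821 shared), 6 and 60 with neutrophil and secretory scores as covariates (1 and 2 shared), 1455 and 1196 at an adjusted p under 0.01, 1614 and 1361 at 2-fold or more, and 856 and 572 with the GAPDH covariate (851 and 562 shared). Genes higher in a fit of genes alone were 1128, and 752 probe sets were lower after scaling to the hybridisation controls with dim probe sets left out, called scaling below (740 shared). Dim probe sets left out alone gave 2621 lower, and 2181 and 2084 for mastitis against endometritis. For mastitis against endometritis they were 109 and 704 up to 120 (98 and 107 shared), 859 lower above 120 (667 shared), 17 and 141 with neutrophil and secretory scores (5 and 2 shared), 1091 and 664 at 0.01, 943 lower at 2-fold or more, and 1251 and 583 after scaling (1213 and 529 shared), with 934 genes higher. For endometritis against healthy, 516 were higher and 15 lower up to 120, 4 lower above 120, and 1 lower with trend and robust moderation, array weights, dim probe sets left out, median centring, genes counted or scaling. Of probe sets called in mastitis against healthy 52.1% were higher, and 73.2% after scaling, 65.5% and 62.2% in the title subsets and 9.09% with neutrophil and secretory scores. For mastitis against endometritis 54.9% became 68.2% after scaling, 13.4% up to 120 and 10.8% with the scores.

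Lists called with an estimated correlation were 0 higher and 0 lower in each comparison. In endometritis against healthy, lists lower were 1 in the fit of 12 arrays and with quantile normalisation and 5 after scaling, and lists higher were 1 with the GAPDH covariate and 1 with macrophage and T cell scores, which remove the T cell list by construction, and 5 without healthy 3 and endometritis 3. With 1 array left out, lists higher ran from 1 (without endometritis 4) to 8 (without endometritis 3), with 5 without healthy 6 or endometritis 1, lists lower from 1 (without healthy 1, healthy 2, mastitis 1, mastitis 4 or endometritis 4) to 3, and probe sets lower from 0 to 1 (without healthy 6). Left-out fits gave 1994 to 2519 higher and 1768 to 2405 lower in mastitis against healthy, 1515 to 2095 and 1100 to 1740 in mastitis against endometritis, and 0.265 to 0.561 for the correlation.

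Single arrays decided some calls, with adjusted p without them in parentheses. In mastitis against healthy these were NCR1, at background in healthy, without healthy 1, 2, 3, 4, 5 and 6, mastitis 2, 5 and 6, endometritis 1, 2, 3, 5 and 6 (0.0535 to 0.0992), PLAUR without healthy 2, 3, 4, 5 and 6, mastitis 2, 3, 4 and 6, endometritis 1, 2 and 4 (0.0547 to 0.11), BLK without healthy 1, 2, 3, 4 and 5, mastitis 4, 5 and 6 (0.0546 to 0.0784), BOLA-DOA without healthy 2, 3 and 4, mastitis 3, 5 and 6 (0.0517 to 0.0584), SAA3 without healthy 4, 5 and 6, mastitis 1, 2, 4 and 6 (0.0566 to 0.0761), LTF without healthy 2 and 4, mastitis 2 (0.0537 to 0.0567), NK and cytotoxic markers without healthy 1, 2, 4 and 5, mastitis 4, 5 and 6, endometritis 4 and 6 (0.0503 to 0.118), antimicrobial and acute phase proteins without healthy 4 and 6, mastitis 1 and 4, endometritis 3 (0.0536 to 0.0947). In mastitis against endometritis they were KLRB1, at background in mastitis, without mastitis 1, 2, 3, 4 and 5, endometritis 1, 2, 4 and 6 (0.0582 to 0.0872), SAA3 without mastitis 1, 2, 4 and 6, endometritis 2, 3, 4 and 5 (0.0562 to 0.0778), BOLA-DOA without mastitis 3, 5 and 6, endometritis 1, 2, 3 and 4 (0.0598 to 0.0754), NUSAP1 without mastitis 1, 2 and 4, endometritis 1, 2, 3 and 4 (0.0514 to 0.0701), PLAUR without mastitis 2, 4 and 6, endometritis 1, 2, 3 and 4 (0.0541 to 0.0825), TCF7 without mastitis 1, 2, 3, 4 and 6, endometritis 1, 2 and 4 (0.0533 to 0.091), VCAN without mastitis 2 and 6, endometritis 1, 2 and 3 (0.0592 to 0.0712), IL1B without mastitis 2, endometritis 1, 2 and 3 (0.0507 to 0.0602), TIMP3 without endometritis 1, 2 and 4 (0.0515 to 0.0612). In endometritis against healthy they were the lists of inflammatory cytokines and chemokines without healthy 1 and 2, mastitis 1, 2, 3, 4 and 6, endometritis 1, 2, 3 and 4 (0.0501 to 0.358), epithelial structure genes without healthy 1, 2 and 3, mastitis 1 and 4, endometritis 4, 5 and 6 (0.0503 to 0.372), T cell markers without healthy 1, 2 and 4, mastitis 4, endometritis 2 and 4 (0.051 to 0.598), NK and cytotoxic markers without endometritis 4 (0.0707).

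With neutrophil and secretory scores as covariates 45 named genes of mastitis against healthy changed sign, none past the threshold, and for members of those lists the covariates take up the difference by construction: NOS2 -1.66, RUBCNL -0.49, SDS -1.48, DNAJC12 1.19, BTN1A1 1.95, ABCG2 3.10, S100B 1.84, SCD 0.89, GPAM 1.51, NCF4 -0.27, LPL 0.52, KRT19 0.73, EPCAM 0.98, KRT7 1.18, CLDN7 2.29, CXCL8 -2.64, IL4R -0.17, LTF 2.25, BOLA-DMA -0.25, BOLA-DMB -0.79, CD55 -1.52, CFD -0.11, C5AR2 -1.08, ALOX15 2.65, PTGER4 -0.35, VAV1 -0.51, CD47 -0.12, ICAM1 -0.20, VEGFA -0.79, SLC16A3 -2.94, ADM -0.85, ACSS2 0.60, NUSAP1 -2.46, TNFRSF1A -0.61, RPL19 0.44, ZFP36 -2.74, DUSP1 -3.41, KLF4 -2.08, JUN -0.21, TIMP1 -2.77, VCAN -3.66, TIMP3 0.50, PLAUR -6.04, TLR2 -2.20, TLR4 -2.55. So did 50 of mastitis against endometritis: RUBCNL -0.20, SDS -1.42, APOBEC3Z1 -0.23, NOS2 -2.04, ELF5 0.54, BTN1A1 2.38, DNAJC12 2.12, ABCG2 3.19, FABP3 0.18, GPAM 1.97, NCF4 -0.13, LPL 0.30, KRT19 1.51, EPCAM 1.36, CLDN7 2.58, CXCL8 -2.44, IL1RN -1.29, HP -0.43, STAT2 -0.00163, BOLA-DMA -0.31, BOLA-DMB -1.05, CD55 -1.93, CFD -0.22, C5AR2 -1.42, ALOX15 2.86, LTA4H 0.15, CD47 -0.25, PLAU -3.85, VEGFA -0.98, ALDOC 1.02, SLC16A3 -3.55, NDUFA4 0.31, FASN 0.00401, SCD 1.74, ACSS2 1.41, NUSAP1 -2.72, TNFRSF1A -0.89, RPL19 0.71, ZFP36 -3.10, KLF4 -1.73, DUSP1 -3.80, JUN -0.39, JUNB -0.61, TIMP1 -2.58, TIMP3 0.57, VCAN -4.19, PLAUR -5.89, IL1B -3.96, TLR2 -2.88, TLR4 -2.90. With the GAPDH covariate the cell cycle list of mastitis against healthy went to -0.39 and the interferon list of endometritis against healthy to -0.21. Neither list was called in the main fit, but both were called downward there by camera at its preset correlation (adjusted p under 0.05).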

Other observations

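The relations between list scores and the tests of the patterns below were chosen after the results were seen, while the counts over other splits of the arrays were planned. Among healthy and endometritis cows, arrays with more macrophage marker RNA had less milk gene RNA: over these 12 arrays the macrophage and mammary secretory scores had r = -0.763 (permutation p = 0.00209, adjusted 0.0585) and rho = -0.783 (permutation p = 0.00372, adjusted 0.104), and r = -0.658 without the 2 arrays farthest from the median. Within healthy arrays r was -0.771 and within endometritis arrays -0.798 (exact permutation p = 0.0361 and 0.0625, adjusted 0.202 and 0.224). Without the 2 farthest arrays these were -0.855 and -0.218, so the value within endometritis rests on 2 arrays. Within mastitis arrays r was -0.489 (exact permutation p = 0.342, adjusted 0.563), and -0.0523 without the 2 farthest. None of the 28 relations in this family passed after adjustment.

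Among the 6 mastitis arrays, neutrophil and macrophage scores had r = -0.968 (exact permutation p = 0.00972, adjusted 0.0907) and rho = -0.829 (exact permutation p = 0.0583, adjusted 0.233), and neutrophil and ribosomal protein scores had r = -0.909 (exact permutation p = 0.0278, adjusted 0.194) and rho = -0.886 (exact permutation p = 0.0333, adjusted 0.163). Without the 2 farthest arrays r was -0.778 and -0.888. In the same mastitis arrays the neutrophil and mammary secretory scores had r = 0.575 (exact permutation p = 0.208, adjusted 0.402) and rho = 0.886 (exact permutation p = 0.0333, adjusted 0.163), and r = 0.332 without the 2 farthest.

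Each comparison was repeated over 100 splits of its 12 arrays into groups of 6, the real split included. For mastitis against healthy 1 of 100 splits, the real one, gave as many probe sets as the real 4689, the highest other being 2348. Chance is thus an unlikely source of that number. For lists 2 of 100, the real split included, gave as many as the real 21, the highest other being 23. Such a number of lists is uncommon among the splits, but chance is not excluded for it. It also holds only at camera's preset correlation, since 0 lists were called with an estimated one. For mastitis against endometritis 1 of 100, the real one, gave as many probe sets as the real 3493, the highest other being 1320, so chance is unlikely there as well. However, 15 of 100 gave as many lists as the real 19, the highest other being 21, so chance cannot be excluded for the number of lists. For endometritis against healthy 100 of 100 splits gave at least the real 0 probe sets, as any split must, so that count tests nothing, and the highest other gave 232. There 72 of 100 gave at least the real 6 lists, the highest other being 22, so chance cannot be excluded for the lists. The split with 232 probe sets set healthy 1, 3 and 6 with endometritis 4, 5 and 6 against the rest, and may point to a structure of the samples, but it was picked as the highest of all and no structure was tested. On the second principal component 5 of its arrays lay from 20.47 to 61.90 and healthy 3 at -35.69.

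Oxidative phosphorylation genes were lower in endometritis, with a list median of -0.41, by camera with its preset correlation (adjusted p = 1.2e-10) and not with an estimated one (adjusted p = 0.999), by fry or by the score after adjustment (0.303). Scaling by the authors would move other genes of the same level as far, but the score of the list changed by -0.34 ± 0.14 (SE) relative to the genes nearest in mean level (exact permutation p = 0.0368). A different share of macrophages and T cells would take the difference away when their scores are covariates, but it was -0.35 ± 0.11 (SE) then and -0.38 ± 0.12 before, in fits of the 12 arrays compared. A difference in RNA quality would take it away when the GAPDH difference is a covariate, but it was -0.41 ± 0.14 (SE) then. The difference thus remained in each of these tests of the 12 arrays. They cannot decide against these explanations, because the shift itself was not told apart from chance. In fits of all 18 arrays, where mastitis arrays widen the error, the difference was -0.46 ± 0.19 and -0.33 ± 0.24 with these covariates and -0.38 ± 0.22 without. Over all alternatives the adjusted p of this list ran from 2.03e-17 to 0.999. Chance is not excluded, since 72 of 100 splits of these arrays gave at least the real 6 called lists. This list had the smallest camera p of all lists. The tests above used the same arrays, so they do not count against chance. A lower level of these genes in milk cells of cows with endometritis may also account for it, as may stage of lactation, and neither was tested.

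Among mastitis arrays the oxidative phosphorylation score differed from cow to cow. A different share of neutrophils may account for this, since the score had r = -0.967 with the neutrophil score (exact permutation p = 0.00694, adjusted 0.0907) and rho = -0.943 (exact permutation p = 0.0167, adjusted 0.163), with r = -0.818 without the 2 farthest arrays, but this did not pass after adjustment over 28 relations. A difference in RNA quality cannot be told apart either, as r with the GAPDH difference over the 6 arrays was 0.517 (exact permutation p = 0.285), which decides neither way. No biological explanation within mastitis was tested, because the labels give no further grouping of the cows.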
